A study of Arabidopsis thaliana with 48 samples.

How the data were processed

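The study measured messenger RNA in Arabidopsis leaves after inoculation with the powdery mildew fungus Bgh. The libraries cover 2 plant lines (pps and B12), 2 isolates (K1 and A6), 4 times and 3 biological replicates, 48 libraries in 16 groups. Polyadenylated RNA was made into TruSeq libraries and sequenced on a HiSeq instrument, per the labels' protocols. The submitters' processing notes name CASAVA 1.8, TopHat 1.3.2 and bedtools 2.13.2 with the TAIR10 genome. They do not state the role of each tool, the filters, the strand setting or the treatment of reads that match several places. The deposited table holds raw counts per locus, whole numbers whose sums differ between libraries, with 1 column per library and no column of no sample.

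The table lists 32678 loci, of which 31912 matched a locus tag of the TAIR10.1 gene table used for symbols and positions. The position of loci is given in TAIR10.1. Near-identical copies such as the PDF1.2, CYP71A12 and CYP71A13, AOC, LHCB, EDS1 and EDS1B, and CRK genes may share reads, and the counting is not stated to use strand, so values of such genes and of overlapping or antisense genes are uncertain. The MLA1 transgene has no locus in the table. The mutations of PEN2, PAD4 and SAG101 are in all libraries, so their transcripts cannot check the labels. The lines were checked through AT5G35935 and AT3G29644, whose levels in the lines did not overlap in any of the 48 libraries. These loci had the largest decrease and increase between the lines under A6 in the same data. For the A6 libraries their separation was therefore largely fixed by the choice, and it cannot show which line carries MLA1. Another locus that differed between the lines, IQD28, did overlap (6.25 to 21.4 CPM in B12 and 20 to 31.7 in pps). No pair of replicates was a copy: the smallest chi-square per degree of freedom between replicates was 14.

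Genes were filtered with filterByExpr of edgeR 4.0.16 (R 4.3.3) over the 16 groups with a minimum count of 10, which kept 22092 loci and left out 10586. Counts were scaled by TMM, with factors between 0.88 and 1.10, and a gene was called at an edgeR quasi-likelihood Benjamini-Hochberg adjusted p below 0.05, two-sided. The avirulence and time comparisons came from 1 fit over 48 libraries with a level for each combination of virulence and time and with additive terms for line and isolate. The labels name virulence by time as the modelled factor, and the additive terms were a choice made here. Folds of these comparisons are adjusted for those terms and can differ from the ratio of the means printed beside them. The terms are held constant over time, although the isolate effect in pps differed between times for 1312 genes. For such genes the fitted avirulence change at a time can carry part of the isolate effect of other times. The comparisons of lines under A6 and of isolates in pps were averages over 4 times in a fit with 16 group means, so their log2 fold changes weight times equally and can differ from the ratio of pooled CPM. Whether the avirulence effect was equal at 4 times was tested with 3 degrees of freedom.

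The 21 gene lists cover salicylic acid, jasmonate, ethylene, tryptophan and camalexin, early pattern-triggered response, oxidative stress and cell death, NLR receptors and their regulators, cysteine-rich receptor-like kinases, ER folding and secretion, phenylpropanoid and lignin, flavonoid, powdery mildew susceptibility, photosynthesis, circadian clock, abscisic acid and drought, heat shock, senescence, and guard cell, epidermis, vascular and dividing cell markers. They were fixed with the panel of 15 genes, the tests and the rule for named genes before the data were examined. Each list was tested by camera in limma 3.58.1 with a preset correlation of 0.01 in 7 contrasts, with Benjamini-Hochberg adjustment over the 147 tests, and beside it with an estimated correlation and with fry. Named genes were the panel, the 8 genes per direction with the largest change in each avirulence comparison (5 in the others) among called genes with a mean log2 CPM of at least 1 and, for avirulence, all avirulent libraries apart from all virulent ones, and up to 4 members per list by smallest adjusted p. The text names fewer in the order of that rule. The result of 1 such gene is not reported.

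Alternatives were DESeq2 1.42.0 size factors, the DESeq2 test, no filter on low counts, a robust prior, the replicate number as a block, no terms for line and isolate, an interaction contrast, contrasts within the same line or the same isolate, an absolute log2 fold change of at least 1, and leaving out each library in turn. Added after the data were seen were fits without loci in runs of raised neighbours, without 2 libraries rich in ribosomal RNA and without 4 libraries with a raised region. Other splits of the libraries into groups of the same sizes were drawn per comparison, 40 with the real split, a number set by computing time.

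The tests were tried on simulated data. Each gene was drawn independently around 1 mean over all 48 libraries, with the trended dispersion. Apart from library size, only the planted changes differed between libraries. Effects of time, line and isolate, gene-specific spread and runs of raised loci were absent. The shares below therefore do not give the error rates in the real data. For the avirulence comparison at 18 hpi (21675 genes), 26% of genes changed 1.5-fold, 78% changed 2-fold and 98% changed 4-fold were recovered, and 2.11% of calls were false. For the virulent time comparison at 12 hpi the shares recovered were 78%, 96% and 100%, with 4.17% of calls false, and for the isolates in pps 84%, 100% and 100%, with 3.03% of calls false. DESeq2 recovered 72% of genes raised 2-fold at 18 hpi with 13.4% of its calls false. Over 21657 genes, camera returned 1.27e-95 for a simulated list raised 2-fold and 0.983 for an unchanged list.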

Results

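RNA sequencing of leaves was used to follow Arabidopsis thaliana after inoculation with Blumeria graminis f. sp. hordei (Bgh), the powdery mildew fungus of barley, for which Arabidopsis is not a host. Plants of the line called pps were Col-0 with mutations in PEN2, PAD4 and SAG101, genes that limit growth of this fungus on Arabidopsis. Plants of the line called B12 had the same mutations and also expressed the barley immune receptor MLA1 with an HA tag. Leaves received isolate K1, whose effector AVRA1 is recognised by MLA1, or isolate A6, which has other effectors of the same class. Material was sampled at 6, 12, 18 and 24 h post inoculation (hpi), which gave 16 groups of 3 biological replicates and 48 libraries. The combination of B12 with K1 was avirulent per the labels (3 libraries per time), and the other 3 combinations were virulent (9 libraries per time). Total counts per library ranged from 25695433 to 79139648, and between 22276 and 23822 loci had at least 1 count. Of 32678 loci, 22092 passed the filter on low counts and were tested. Replicates of a group had correlations of log2 CPM between 0.947 and 0.981. Values are TMM-normalised CPM as mean ± SD, log2 fold changes are given with their SE, and adjusted p-values are from edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment unless another test is named.

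The question of the main comparison was how leaves in which MLA1 met its effector differed from leaves in virulent interactions. At 18 hpi several panel genes of defence stood higher in the avirulent interaction. WRKY33, a transcription factor that activates camalexin synthesis, was at 170 ± 37.3 CPM in the avirulent libraries (n = 3) against 60.4 ± 9.66 in the virulent ones (n = 9), a 3.18-fold difference (edgeR adjusted p = 1.04e-09). PAD3, which makes the last step to the phytoalexin camalexin, was 6.31-fold higher (432 ± 125 against 97.8 ± 26.4 CPM, edgeR adjusted p = 1.22e-08). ACS6, an enzyme of ethylene synthesis, was 4.34-fold higher (112 ± 26.7 against 29 ± 3.94 CPM, edgeR adjusted p = 6.82e-10). RBOHD, the NADPH oxidase of the defence-related oxidative burst, was 2.23-fold higher (206 ± 25.7 against 103 ± 14.5 CPM, edgeR adjusted p = 4.08e-09).

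At this time 3345 genes differed, 2234 higher and 1111 lower in the avirulent interaction (edgeR adjusted p below 0.05). In 1741 of them all 3 avirulent libraries lay beyond all 9 virulent ones, which a random split of 12 libraries gives for 0.909% of genes, a share for all tested genes and not for those already called. The genes with the largest increases and no overlap between libraries were the kinase gene MAPKKK19 (log2 fold change 4.24 ± 0.51, edgeR adjusted p = 4.47e-08), the transcription factor gene MYB15 (4.18 ± 0.56, 4.22e-07), the NADPH oxidase gene RHD2 (4.02 ± 0.63, 6.97e-06) and the sterol desaturase gene CYP710A1 (3.51 ± 0.52, 2.77e-06). Among genes without overlap and with a mean log2 CPM of at least 1, the largest decreases were smaller. AT5G39520 fell by 1.45 ± 0.47 on the log2 scale (edgeR adjusted p = 0.0276), the B-box gene BBX16 by 1.37 ± 0.36 (0.00715) and AT4G34760 by 1.34 ± 0.27 (0.000297). Called genes with overlap, such as SWEET15 and ASN1 below, are not in this ranking. The call of AT5G39520, a locus in a run of raised neighbours described below, ended without replicate 1 or 2 of B12 with K1 (edgeR adjusted p = 0.113 and 0.0782) and without replicate 3 of pps with K1 (0.119). Leaving out replicate 1 or 2 of B12 with K1 reduced the number of called genes to 1872 or 2130. The contrast with pps under the same isolate alone gave 5047 genes.

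**Figure D1:**
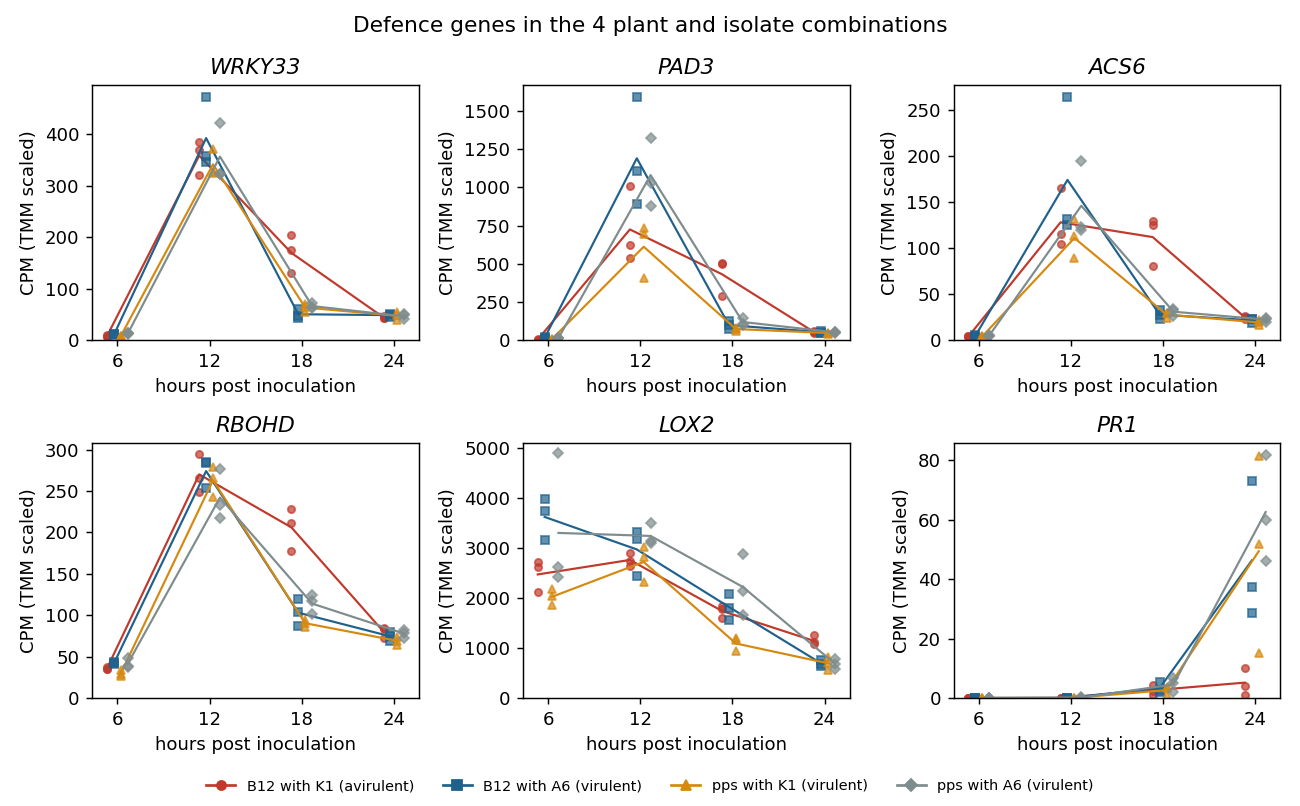
TMM-normalised CPM of WRKY33, PAD3, ACS6, RBOHD, LOX2 and PR1 (linear axes, 1 panel per gene) against hours post inoculation; each point is 1 library, shifted sideways by combination, and lines join the means of 3 replicates per combination of line and isolate. At 18 hpi the 3 libraries of B12 with K1 averaged 170 CPM for WRKY33 and 432 CPM for PAD3, above the virulent means of 60.4 and 97.8 CPM, and at 24 hpi they averaged 5.18 CPM for PR1 against 52.8 CPM.

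The gene groups fixed beforehand showed where the 18 hpi increase was concentrated. Of 25 genes of tryptophan, camalexin and indole glucosinolate metabolism, 21 rose and none fell, and 21 also passed when adjusted over the list alone (camera adjusted p = 3.97e-25, and adjusted p = 0.0416 with an estimated correlation). Among them the cytochrome P450 gene CYP81F2 was 3.73-fold, the anthranilate synthase gene ASA1 3.26-fold and the transporter gene PEN3 2.47-fold higher (edgeR adjusted p = 1.91e-10, 1.39e-09 and 2.48e-09). Of 36 genes of the early response to microbial patterns, 23 rose, none fell and 13 did not pass. Adjusted over the list alone, 27 were higher (camera adjusted p = 5.04e-24, and adjusted p = 0.0393 with an estimated correlation). SZF1 was at 90.9 ± 15 against 34 ± 3.63 CPM, ZAT10 at 40.8 ± 9.35 against 11.3 ± 2.17 and WRKY40 at 70 ± 16.2 against 16 ± 4.63. In the ethylene list 13 of 23 genes rose and none fell. Adjusted over the list alone, 14 were higher and 1 lower (camera adjusted p = 1.46e-12, and adjusted p = 0.0071 with an estimated correlation). The response factor gene ERF1A was 6.38-fold higher (edgeR adjusted p = 1.3e-11) and the ethylene-forming oxidase gene ACO4 3.66-fold higher (edgeR adjusted p = 2.87e-10).

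Of 30 jasmonate genes, 18 rose at 18 hpi and none fell. Adjusted over the list alone, 20 were higher (camera adjusted p = 3.99e-13, but adjusted p = 0.212 with an estimated correlation). OPCL1, of jasmonate synthesis, rose 3.69-fold (197 ± 26.3 against 70.7 ± 20.8 CPM), JAZ1, a repressor of jasmonate responses, 6.12-fold (73.3 ± 19.4 against 17.9 ± 7.48) and the lipoxygenase gene LOX4 6.72-fold (48 ± 12 against 12 ± 5.28), folds that are adjusted for line and isolate and exceed the ratio of the means. The oxidative stress and cell death list had 14 of 26 genes higher and none lower, 16 when adjusted over the list alone (camera adjusted p = 5.65e-10, but adjusted p = 0.161 with an estimated correlation). Among them were the mitochondrial BCS1 (3.25-fold) and RBOHD. In the list of endoplasmic reticulum (ER) folding and secretion 8 of 20 rose and none fell, 9 when adjusted over the list alone (camera adjusted p = 2.25e-06, but adjusted p = 0.472 with an estimated correlation). They included the syntaxin genes SYP122 (2.86-fold) and PEN1 (2.4-fold), which act in secretion at fungal entry sites, and the stress regulator bZIP60 (2.3-fold). Of 13 cysteine-rich receptor-like kinase genes 4 rose and none fell, and 4 when adjusted over the list alone (camera adjusted p = 0.0092, but adjusted p = 0.602 with an estimated correlation), with CRK11 highest at 3.26-fold.

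In the salicylic acid list at 18 hpi 4 of 28 genes rose, none fell and 24 did not pass, the same numbers when adjusted over the list alone (camera adjusted p = 0.0582). CBP60g, a regulator of salicylic acid synthesis, was 2.31-fold higher (edgeR adjusted p = 7.27e-06) and the transporter gene EDS5 2.1-fold higher (edgeR adjusted p = 0.000802). The marker gene PR1 was at 2.59 ± 1.64 CPM in avirulent and 3.52 ± 1.8 in virulent libraries (edgeR adjusted p = 0.805), and the synthesis gene ICS1, a locus in a run of raised neighbours, at 65.2 ± 16.4 and 58.9 ± 10.8 CPM (edgeR adjusted p = 1). In the phenylpropanoid list 6 of 17 rose and none fell, with 6 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.055), including CCR2 (8.94-fold) and CAD5 (2.83-fold). The CAD5 call ended in the fit without line and isolate terms (edgeR adjusted p = 0.0785). In the list of powdery mildew susceptibility genes 2 of 10 rose and 1 fell (4 and 1 when adjusted over the list alone, camera adjusted p = 0.0823), with MLO6 2.85-fold and the callose synthase gene PMR4 1.49-fold higher.

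Lists for other processes moved little at 18 hpi. None of the 10 flavonoid genes passed (0 adjusted over the list alone, camera adjusted p = 0.107), nor any of 10 guard cell (0.256), 12 vascular (0.9) or 7 dividing cell markers (0.482). Of 17 circadian clock genes 2 rose and 1 fell (3 and 1 when adjusted over the list alone, camera adjusted p = 0.74), with the RNA-binding protein gene GRP8 1.79-fold higher. Of 19 abscisic acid and drought genes 5 rose and none fell (5 when adjusted over the list alone, camera adjusted p = 0.292), among them the abscisic acid hydroxylase gene CYP707A3 at 2.97-fold. In the senescence list 1 of 10 rose and 2 fell (2 and 2 when adjusted over the list alone, camera adjusted p = 0.212), with the regulator gene NAP 2.69-fold higher. The 2 that fell, SWEET15 and ASN1, each stood high in 1 virulent library, and their calls ended without it (edgeR adjusted p = 0.205 without replicate 1 of pps with K1 and 0.594 without replicate 3 of B12 with A6). The call of ASN1 also ended without replicate 1, 2 or 3 of B12 with K1 (0.0655, 0.103 and 0.0619) and against the same isolate only (0.964), and SWEET15 had a log2 fold change of 0.00 within the line, where it had no counts. Single members passed in 4 further lists. HSP90.2 was the member higher among 19 genes for NLR receptors, the class of MLA1, and their regulators (log2 fold change 0.33 ± 0.09, edgeR adjusted p = 0.013, camera adjusted p = 0.113 for the list), and its call ended without replicate 1 or 2 of B12 with K1 (0.0857 and 0.0558) and against the same isolate only (0.0511). LHCB2.2, an antenna protein gene in a run of raised neighbours, fell by 1.08 ± 0.37 on the log2 scale (edgeR adjusted p = 0.038) among 40 photosynthesis genes (0 adjusted over the list alone, camera adjusted p = 0.0279, but adjusted p = 0.743 with an estimated correlation). Its call ended without replicate 1 or 2 of B12 with K1 (0.164 and 0.115), replicate 3 of B12 with A6 (0.175) or replicate 1 of pps with K1 (0.0606). The remaining members were 1 of 9 heat shock genes, higher (camera adjusted p = 0.996), and 1 of 6 epidermis and trichome markers, lower (camera adjusted p = 0.055).

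**Figure D2:**
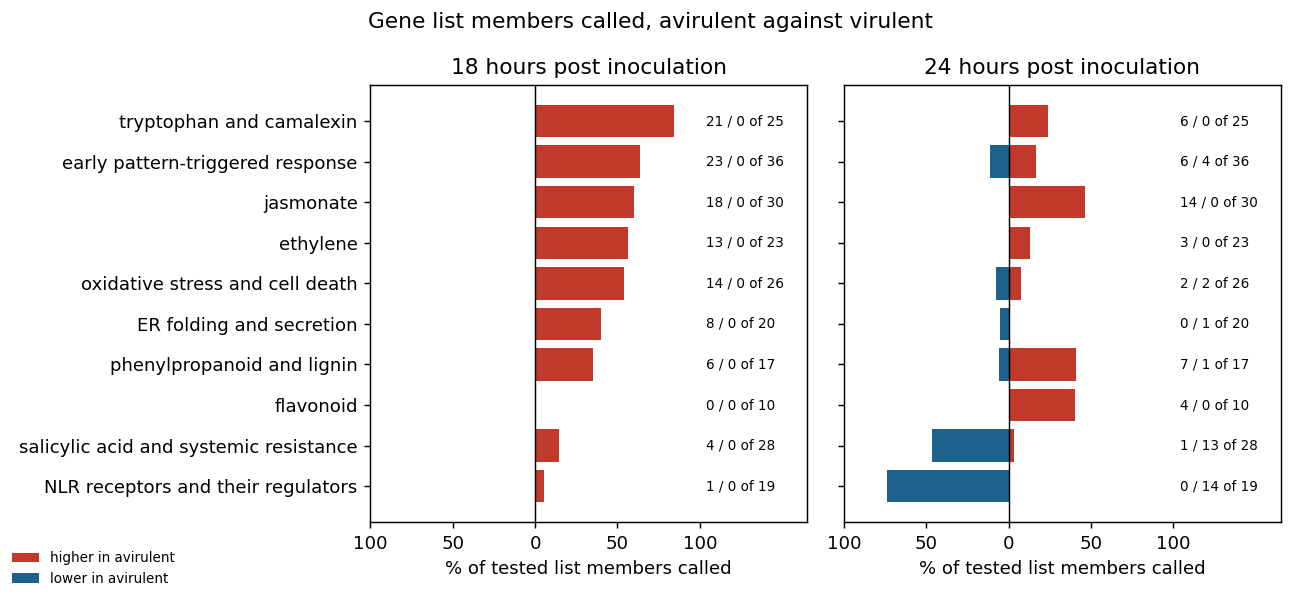
Percent of tested members of 10 gene lists called higher (right of 0) or lower (left of 0) in the avirulent than in the virulent interactions at 18 and 24 hpi, with the numbers higher / lower of tested written beside each bar. At 18 hpi 21 of 25 tryptophan and camalexin genes were higher, and at 24 hpi 14 of 19 genes for NLR receptors and their regulators were lower.

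At 24 hpi the direction for salicylic acid genes was downward in the avirulent interaction. PR1 stood at 5.18 ± 4.64 CPM (n = 3) against 52.8 ± 23.5 CPM in the virulent interactions (n = 9), a 6.04-fold difference (edgeR adjusted p = 0.0078). DMR6, which encodes a salicylic acid hydroxylase, was 3.69-fold lower (11.9 ± 2.19 against 42.3 ± 5.87 CPM, edgeR adjusted p = 5.61e-05). Of 28 genes of the salicylic acid list 13 fell, 1 rose and 14 did not pass. When adjusted over the list alone, 16 were lower and 1 higher (camera adjusted p = 1.93e-09, but adjusted p = 0.332 with an estimated correlation). Further members that fell were NIMIN2 (4.97-fold), NPR4 (2.03-fold) and NPR1 (1.39-fold), all parts of salicylic acid signalling. Of 19 genes for NLR receptors and their regulators 14 fell and none rose, also when adjusted over the list alone (camera adjusted p = 1.67e-13, and adjusted p = 0.0416 with an estimated correlation). The NLR gene ZAR1 was at 109 ± 3.78 against 190 ± 15.3 CPM (edgeR adjusted p = 0.000263) and the signalling gene NDR1 at 5.07 ± 0.556 against 9.4 ± 1.19 CPM (edgeR adjusted p = 0.000631). EDS1B had the largest decrease of the list (log2 fold change -2.97 ± 0.46, edgeR adjusted p = 3.51e-05) and lay in a run of raised neighbours. PAD4, mutated in all plants, was at 3.94 ± 0.147 against 7.45 ± 0.893 CPM (edgeR adjusted p = 0.000204).

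Of 30 jasmonate genes 14 rose at 24 hpi and none fell. When adjusted over the list alone, 18 were higher (camera adjusted p = 9.36e-09, but adjusted p = 0.365 with an estimated correlation). JAZ9 was 2.16-fold higher (214 ± 30.4 against 126 ± 20.4 CPM, edgeR adjusted p = 0.000227) and LOX2 2.11-fold higher (1140 ± 93.4 against 691 ± 89.3 CPM, edgeR adjusted p = 0.00103). Both folds exceed the ratio of the means through the terms for line and isolate, which are constant over time. In pps at 24 hpi LOX2 was at 694 ± 135 CPM under K1 and 687 ± 99.6 under A6. PDF1.2a, not called, had a fitted log2 fold change of 0.90 although its mean was lower in the avirulent libraries (1760 ± 473 against 2160 ± 494 CPM). Rises at 24 hpi may therefore be overstated for genes whose isolate effect changed over time. In the phenylpropanoid and lignin list 7 of 17 rose and 1 fell, with 9 higher and 2 lower when adjusted over the list alone (camera adjusted p = 3.9e-06, but adjusted p = 0.212 with an estimated correlation). Among those that rose were the methyltransferase gene COMT1 at 1.7-fold and CAD5 at 2.75-fold. Of 10 flavonoid genes 4 rose and none fell. When adjusted over the list alone, 5 were higher and 1 lower (camera adjusted p = 0.00257, but adjusted p = 0.489 with an estimated correlation). The flavonoid member with the smallest adjusted p was 4CL3 (148 ± 30.6 against 61.1 ± 21.7 CPM), with a log2 fold change of 0.88, whose call ended without replicate 2 of B12 with K1 (0.70, edgeR adjusted p = 0.0925) and without the 4 libraries with a raised region on chromosome 3 (0.82, adjusted p = 0.0622). Of 25 tryptophan and camalexin genes 6 rose and none fell, 7 when adjusted over the list alone (camera adjusted p = 2.47e-05, but adjusted p = 0.489 with an estimated correlation), with TSB1 1.78-fold and GSTF6 2.11-fold higher. Of 19 abscisic acid and drought genes 3 rose, 6 when adjusted over the list alone (camera adjusted p = 6.63e-05, but adjusted p = 0.285 with an estimated correlation). RD29A (log2 fold change 1.09) lost its call without replicate 3 of B12 with K1 (edgeR adjusted p = 0.0753).

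Several lists went both ways or changed in few members at 24 hpi. Of 36 early pattern-response genes 6 rose and 4 fell (8 and 6 when adjusted over the list alone, camera adjusted p = 0.811). The chitin receptor gene CERK1 fell to 16.7 ± 0.672 from 28.2 ± 2.14 CPM, while MYB15 stood 6.83-fold higher. Of 26 oxidative stress and cell death genes 2 rose and 2 fell (3 and 2 when adjusted over the list alone, camera adjusted p = 0.0544). The metacaspase gene MC2 was 3.57-fold lower and the peroxidase gene PRX71 2.73-fold higher. Of 13 cysteine-rich receptor-like kinase genes 3 fell and none rose, with 4 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.00671, but adjusted p = 0.577 with an estimated correlation), among them CRK45 (1.97-fold). In the ER list 1 of 20 fell and none rose, with 6 lower when adjusted over the list alone (camera adjusted p = 0.000967, but adjusted p = 0.577 with an estimated correlation). The member called over all genes was SNAP33, whose call ended without replicate 1 or 3 of B12 with K1 (edgeR adjusted p = 0.0681 and 0.0734). Of 10 powdery mildew susceptibility genes 3 fell and none rose, also over the list alone (camera adjusted p = 0.154), but 1 of the 3, PMR6, lies in the raised region of chromosome 3 and had a log2 fold change of 0.17 without the 4 libraries raised there. MLO2, whose loss confers mildew resistance, stood at 110 ± 5.84 against 198 ± 21.1 CPM (edgeR adjusted p = 3.56e-06). Of 23 ethylene genes 3 rose and none fell (4 and 1 when adjusted over the list alone, camera adjusted p = 0.489). Of 17 clock genes 1 rose and 1 fell (the same when adjusted over the list alone, camera adjusted p = 0.685), with TOC1 1.61-fold lower. No photosynthesis, heat shock, guard cell, epidermis, vascular or dividing cell marker gene passed the edgeR test (camera adjusted p = 0.0824, 0.249, 0.292, 0.116, 0.297 and 0.221), and 3 of 10 senescence genes rose (camera adjusted p = 0.106).

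In total 1936 genes differed at 24 hpi, 960 higher and 976 lower (edgeR adjusted p below 0.05). Rankings in this paragraph cover called genes with a mean log2 CPM of at least 1 and no overlap between avirulent and virulent libraries. Outside this rule, CYP94B3 had a log2 fold change of 5.67 at 0.18 ± 0.184 against 0.0557 ± 0.073 CPM. RNS1, a secreted ribonuclease gene, had the largest increase (12 ± 4.3 against 0.882 ± 0.57 CPM, log2 fold change 5.80 ± 0.78, edgeR adjusted p = 3.39e-06). That fitted change exceeds the ratio of these means through the terms for line and isolate, and it was 3.76 without them. The next genes by size of increase under this rule were AT1G55200, MRE11 and the adjacent AT2G05420, AT2G05410 and AT2G05400. All 5 lie in runs of neighbouring loci raised together in single libraries. Counts of the last 3 were the same multiple of 4, 5 and 7 in 46 of 48 libraries, so they amount to 1 measurement. The calls of AT1G55200 and MRE11 each rested on 1 library and ended without replicate 2 and replicate 3 of B12 with K1 (edgeR adjusted p = 0.239 and 0.248). The largest decreases were AT3G55470, HEXO1, PBL1 and PDIL1-3, between -5.31 and -3.66 on the log2 scale. All 4 lie on chromosome 3 in the region described in the next paragraph, and without the 4 libraries raised there their log2 fold changes were -1.03, -1.11, -0.58 and -0.69 and none was called. Outside such runs the largest decreases were AT5G55450 (log2 fold change -3.13 ± 0.44) and AT5G03350 (-2.73 ± 0.55). The number of called genes was 1112 without replicate 2 of B12 with K1 and 1247 without the 4 libraries. An interaction contrast, the isolate difference in B12 minus that in pps, gave 666 genes, 159 higher and 507 lower. It does not guard against the raised region, which lies in libraries of B12 with A6 and of pps with K1, both subtracted in it. The log2 fold changes of AT3G55470, HEXO1, PBL1 and PDIL1-3 were -9.15, -8.60, -8.64 and -6.61 in it. How many of the 666 genes lie in that region was not counted. Genes named above that lost their call in the interaction contrast included PR1 (log2 fold change -2.80, edgeR adjusted p = 0.0575), PAD4 (-0.75, 0.0539) and NDR1 (-0.73, 0.0624). So did CRK45 (-1.02, 0.0599), 4CL3 (0.95, 0.0542), CYP94B3 (1.96, 0.79), LOX2 (0.71, 0.162), CAD5 (0.88, 0.128) and TSB1 (0.50, 0.229). The others were GSTF6 (0.61, 0.268), RD29A (0.87, 0.181), SNAP33 (-0.43, 0.293), AT1G55200 (3.13, 0.268), AT2G05400 (3.19, 0.0738), AT2G05410 (3.19, 0.0678) and AT2G05420 (3.19, 0.0643).

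Counts of neighbouring loci rose together in single libraries in many places of the genome. Counted as 5 or more of 10 adjacent loci at least 3-fold above the lowest replicate of the same group, 3505 loci lay in such runs, against a mean of 0.85 after shuffling their order. Runs held 11% of tested loci but 60.3% of the genes called at 6 hpi and 64.7% of those at 12 hpi, against 5.95% at 18 hpi and 19.6% at 24 hpi. A large effect at 24 hpi was on chromosome 3 between positions 20342753 and 20709244 of TAIR10.1, a region of 106 loci. It was raised in replicates 1 and 3 of B12 with A6 and replicates 1 and 2 of pps with K1. PMR6, a pectate lyase-like gene of mildew susceptibility inside this region, was called lower in the avirulent libraries (11.8 ± 0.37 against 83.5 ± 88.4 CPM), and without those 4 libraries its log2 fold change was 0.17 (edgeR adjusted p = 0.931). The share of counts on ribosomal RNA loci was 11.2% in replicate 2 of B12 with A6 at 12 hpi and 5.47% in replicate 3 of pps with A6 at 12 hpi.

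**Figure D3:**
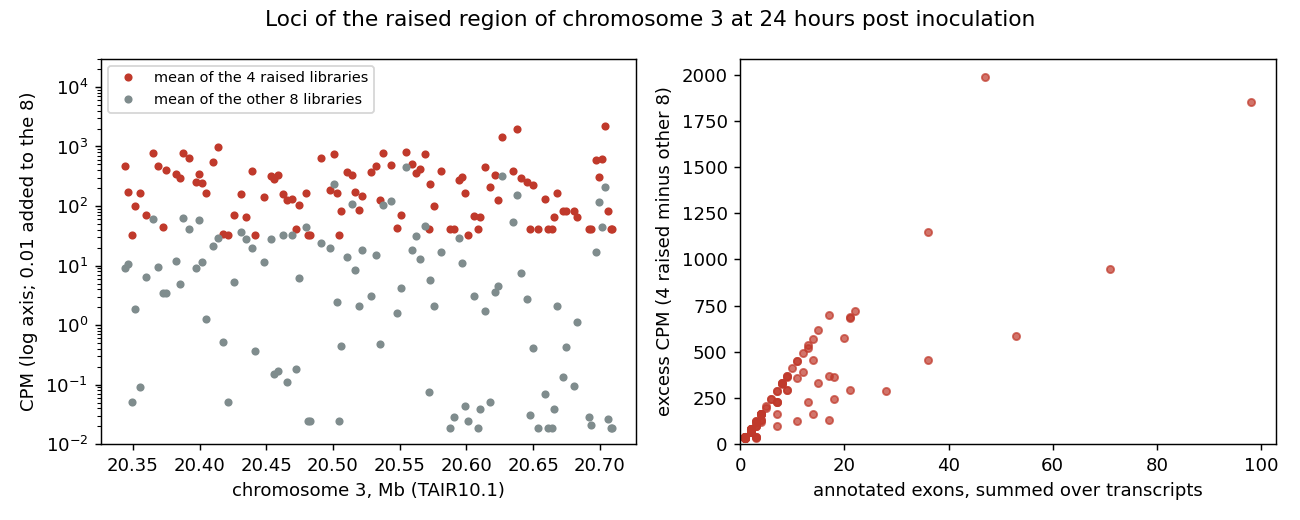
Left, CPM (log axis) of each locus against its position on chromosome 3 in Mb, with means of the 4 raised libraries in red and of the 8 other libraries of 24 hpi in grey, a small constant added to the grey values so that 0 can be drawn; right, the difference of these means in CPM against the number of annotated exons summed over the transcripts of the locus (linear axes). The excess follows the number of exons (Spearman rho 0.928 over 105 loci, permutation p = 1e-04, the smallest the 10000 permutations can give), with a median of 33.3 CPM per exon.

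Before 18 hpi few genes differed between avirulent and virulent interactions. At 6 hpi 58 genes passed, 52 higher and 6 lower (edgeR adjusted p below 0.05), and with DESeq2 median-of-ratios size factors the split was 58 higher and 17 lower. The largest changes without overlap were AUG7 (8.74 ± 6.85 against 3.41 ± 0.243 CPM) and SAUL1, in a run of raised neighbours (15.6 ± 12.9 against 6.7 ± 0.446 CPM), both of which rested on replicate 3 of B12 with K1: without it their log2 fold changes of 1.24 and 1.22 were 0.38 and 0.30. The methylesterase gene MES18 was the largest decrease without overlap (10.9 ± 0.492 against 19.7 ± 5.29 CPM, edgeR adjusted p = 0.0148). Its call ended without replicate 3 of B12 with K1 and without replicate 2 of B12 with A6 (log2 fold changes -1.20 and -1.06). Of the lists, 1 of 17 clock genes, RVE1, and 2 of 12 vascular markers, CESA7 and XCP2, were called higher (1 and 3 when adjusted over the list alone, camera adjusted p = 0.996 and 0.0459, the latter 0.489 with an estimated correlation). RVE1 and CESA7 lie in runs of raised neighbours. Without replicate 3 of B12 with K1 these had log2 fold changes of -2.18, 0.10 and 0.30, and the call of XCP2 also ended without replicate 2 of B12 with A6 or of pps with K1 (0.94 and 0.87). The salicylic acid list had no called gene over all genes, 4 higher and 1 lower when adjusted over the list alone (camera adjusted p = 3e-04, but adjusted p = 0.538 with an estimated correlation), and the 40 photosynthesis genes had a median log2 fold change of -0.15 (camera adjusted p = 0.000895, but adjusted p = 0.644 with an estimated correlation). In the other lists no gene passed over all genes, while adjusted over the list alone 2 NLR-related genes and 1 dividing cell marker were higher and 1 tryptophan and 1 senescence gene lower. Without loci in runs 10 genes were called, and leaving out single libraries gave between 32 and 205.

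At 12 hpi 17 genes passed, all higher (edgeR adjusted p below 0.05; 1308 genes had an unadjusted p below 0.05, and DESeq2 called 61 genes, 35 higher and 26 lower). The sulfate transporter gene SULTR3;2 (31.7 ± 48.4 against 0.527 ± 0.443 CPM) and AT4G02900 (34.1 ± 48.7 against 2.62 ± 0.351 CPM), both called and without overlap, lie in a run of raised neighbours in replicate 3 of B12 with K1. Without that library no gene was called by edgeR (944 at an unadjusted p below 0.05), and the log2 fold changes of SULTR3;2 and AT4G02900 went from 5.96 and 3.37 to 2.93 and 0.87. Of the panel genes, WRKY33 was at 359 ± 33.2 against 364 ± 52 CPM, PAD3 at 725 ± 251 against 961 ± 351, RBOHD at 270 ± 22.9 against 260 ± 24.4, ACS6 at 128 ± 32.5 against 144 ± 53.1, CYP71A13 at 276 ± 137 against 420 ± 231 and PDF1.2a at 9.48 ± 5.28 against 39.6 ± 41.6 (edgeR adjusted p = 0.976, 0.988, 0.908, 1, 1 and 0.966). The panel gene LHCB2.2 had no overlap (1.28 ± 0.112 against 2.88 ± 1.41 CPM) but was not called (log2 fold change -1.50, edgeR adjusted p = 0.291). No list had a called member over all genes, and adjusted over the list alone 2 photosynthesis genes, 1 senescence gene and 1 guard cell marker were lower. Small shifts gave camera adjusted p = 3.58e-06 for the ER list (median log2 fold change 0.23), 2.47e-05 for cysteine-rich receptor-like kinases (0.37), 0.000351 for the early pattern response (0.22) and 0.000895 for NLR receptors and their regulators (0.16). With an estimated correlation the adjusted p was 0.472, 0.439, 0.529 and 0.472.

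Whether the avirulence effect was equal at the 4 times was tested directly, and it differed for 5492 genes (edgeR F test with 3 degrees of freedom, adjusted p below 0.05). WRKY33, PAD3, ACS6 and RBOHD, higher at 18 hpi, were among them (edgeR adjusted p = 5.33e-09, 3.34e-08, 1.27e-08 and 5.91e-07), as were PR1 and PAD4, lower at 24 hpi (edgeR adjusted p = 0.00895 and 2.79e-05). CYP71A13, another camalexin gene, rose 4.3-fold at 18 hpi (215 ± 77.5 against 73.4 ± 32.7 CPM) and had 126 ± 16.5 and 126 ± 21.8 CPM at 24 hpi (edgeR adjusted p = 5.32e-05 for a difference between times). PEN2, mutated in all plants, had a 1.72-fold higher transcript level at 18 hpi (edgeR adjusted p = 5.21e-07) and 25.6 ± 1.47 against 30.7 ± 2.29 CPM at 24 hpi (edgeR adjusted p = 8.18e-08 for a difference between times). For ICS1 equality was not rejected (edgeR adjusted p = 0.35). With interaction contrasts, which let the line and isolate effects change over time, 1759 genes differed between times. Of the 2234 genes higher at 18 hpi, 201 were also higher and 105 lower at 24 hpi, where 97.1 and 98.7 would be shared by independent lists.

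The lines without recognition were compared under isolate A6, averaged over the 4 times, to show what the MLA1 construct line changes by itself. In this average 99 genes differed, 30 higher and 69 lower in B12 (edgeR adjusted p below 0.05). Tested by time, 127, 16, 236 and 217 genes differed at 6, 12, 18 and 24 hpi. At 18 hpi 43 of these were higher and 193 lower in B12, and at 24 hpi 137 were higher and 80 lower. At 24 hpi replicates 1 and 3 of B12 with A6 have the raised region of chromosome 3, and no library of pps with A6 does. How much of the change of direction comes from that region was not tested. AT5G35935 had 0.0835 ± 0.0731 CPM in B12 and 5.11 ± 1.03 in pps (n = 12 each, log2 fold change -6.01 ± 0.23, edgeR adjusted p = 5.9e-20), and over all 24 libraries of each line, K1 included, its ranges were 0 to 0.241 and 3.44 to 6.66 CPM. AT3G29644 was 3.78-fold higher in B12 (3.35 ± 0.602 against 0.902 ± 0.436 CPM, edgeR adjusted p = 7.62e-10), and its ranges over all libraries, 2.21 to 4.21 and 0.182 to 2.09 CPM, did not overlap either. MLA1 has no locus in this table and its own level was not analysed here. No member of the 21 lists passed over all genes, while adjusted over the list alone 2 senescence genes, 1 NLR-related gene and 1 mildew susceptibility gene were higher; the panel genes PR1, WRKY33 and PAD3 had log2 fold changes of -0.61 ± 1.47, -0.10 ± 0.08 and 0.00 ± 0.14. The number of called genes was 50 without the 2 libraries rich in ribosomal RNA, 39 without the 4 libraries raised on chromosome 3 and 237 without replicate 2 of B12 with A6 at 24 hpi.

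Isolate K1 was compared with A6 in pps plants, averaged over the 4 times, to show what the isolates change without the receptor. Flavonoid genes stood higher and jasmonate genes lower under K1. Of 10 flavonoid genes 9 rose and none fell, also when adjusted over the list alone: 4CL3 was 1.71-fold, FLS1 1.77-fold and chalcone synthase (CHS) 1.6-fold higher (edgeR adjusted p = 2.44e-06, 4.43e-06 and 1.88e-05, n = 12 each). Of 30 jasmonate genes 24 fell and none rose, with 26 lower when adjusted over the list alone. They included the defensin gene PDF1.2a (2.82-fold, edgeR adjusted p = 3.43e-05), AOC1 (2.04-fold, 3.43e-05) and LOX2 (1.41-fold, 0.000494). Of 25 tryptophan and camalexin genes 19 fell and none rose, with 22 lower and 1 higher when adjusted over the list alone, TSB1 by 1.51-fold and GSTF6 by 1.66-fold (edgeR adjusted p = 2.08e-06 and 4.13e-06). Phenylpropanoid genes went both ways, 3 of 17 higher and 5 lower (4 and 6 when adjusted over the list alone), with PAL1 1.49-fold higher and CAD5 1.79-fold lower (edgeR adjusted p = 2.98e-07 and 4.37e-06). In the oxidative stress list 11 of 26 fell and none rose (14 lower and 1 higher when adjusted over the list alone), with the peroxidase gene PRX33 1.67-fold lower, and in the early pattern-response list 9 of 36 fell and 1 rose (11 and 1 when adjusted over the list alone).

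In all 3472 genes differed between the isolates in pps, 1529 higher and 1943 lower under K1 (edgeR adjusted p below 0.05). Among called genes with a mean log2 CPM of at least 1, the largest increase was AT1G13609 (4.84 ± 5.84 against 0.709 ± 0.571 CPM, log2 fold change 2.84 ± 0.53, edgeR adjusted p = 0.000344). The largest decreases among them were CYP82G1 (-2.62 ± 0.46, edgeR adjusted p = 0.000177), the jasmonate-regulated JRG21 (-2.20 ± 0.29, 4.37e-06) and the acetyltransferase gene NATA1 (-2.09 ± 0.31, 1.85e-05). AT5G54700, also named among the largest increases and located in a run of raised neighbours, had a log2 fold change of 2.71 that was -0.06 without replicate 2 of pps with K1 at 18 hpi. By time, 643, 2183, 2431 and 298 genes differed between isolates in pps at 6, 12, 18 and 24 hpi, and the isolate effect itself differed between times for 1312 genes. By direction, 181 were higher and 462 lower under K1 at 6 hpi, 1102 and 1081 at 12 hpi, 1110 and 1321 at 18 hpi, and 276 and 22 at 24 hpi, when 2 of the 3 libraries of pps with K1 have the raised region of chromosome 3. In B12 plants, where K1 is recognised, the numbers were 1868, 2563, 2959 and 2990.

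Over time in the virulent interactions most genes changed, and time after inoculation cannot be separated from time of day in this design. From 6 to 12 hpi early immune transcripts rose steeply: WRKY33 went from 11 ± 2.09 to 364 ± 52 CPM (33.4-fold, n = 9 each), PAD3 from 12.2 ± 6.44 to 961 ± 351 (81.2-fold) and ACS6 from 4.71 ± 0.755 to 144 ± 53.1 (30.3-fold; edgeR adjusted p = 3.13e-32, 2.13e-26 and 7.08e-29). Of 36 early pattern-response genes 32 rose and 1 fell (camera adjusted p = 2.74e-13, but adjusted p = 0.178 with an estimated correlation). Of 23 ethylene genes 20 rose and 3 fell (camera adjusted p = 7.52e-07, and adjusted p = 0.0468 with an estimated correlation). All 13 cysteine-rich receptor-like kinase genes rose (camera adjusted p = 0.000143, but adjusted p = 0.472 with an estimated correlation). Photosynthesis genes were lower, 31 of 40 at 12 hpi (camera adjusted p = 7.12e-10, but adjusted p = 0.472 with an estimated correlation), with LHCB3 at 45.3 ± 4.38 against 1330 ± 130 CPM. Clock genes were also lower, 13 of 17 with 3 higher (camera adjusted p = 2.42e-06, and adjusted p = 0.0393 with an estimated correlation), with GRP7 at 192 ± 23.1 against 3670 ± 275 CPM. All these counts were the same when adjusted over the list alone.

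By 24 hpi a later set of defence genes had risen in the virulent interactions. PR1 went from 0.0089 ± 0.0134 to 52.8 ± 23.5 CPM and PDF1.2a, a defensin gene with near-identical copies, from 6.3 ± 4.39 to 2160 ± 494 CPM (edgeR adjusted p = 4.48e-19 and 6.88e-21, n = 9 each). Of 28 salicylic acid genes 24 were higher and 2 lower at 18 hpi (camera adjusted p = 3.73e-05) and 25 were higher and 2 lower at 24 hpi (camera adjusted p = 8.18e-08; adjusted p = 0.489 and 0.406 with an estimated correlation). The jasmonate list split, 8 of 30 higher and 16 lower at 24 hpi (camera adjusted p = 0.146): PDF1.2a rose while AOC2, of jasmonate synthesis, went from 375 ± 109 to 70 ± 8.87 CPM. WRKY33 and PAD3 were at 47.8 ± 5.23 and 51.5 ± 4.59 CPM at 24 hpi, below their 12 hpi levels, a difference not tested. Photosynthesis genes were higher at 24 hpi, 35 of 40 with none lower (camera adjusted p = 1.69e-09, but adjusted p = 0.472 with an estimated correlation). The numbers of genes called against 6 hpi were 16578 at 12 hpi (8201 higher, 8377 lower), 15736 at 18 hpi (7801 and 7935) and 14759 at 24 hpi (7425 and 7334; edgeR adjusted p below 0.05). With an absolute log2 fold change of at least 1 also required, 6745, 5650 and 4991 remained.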

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

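Of the tests on runs of neighbouring loci, the one on exons was planned before its result was seen, and the tests of a regional gain and of shuffled orders were chosen only after the result was seen. Expression of the named genes in the 9 virulent libraries of a time was searched for single libraries far from the other 8. This was so for 28 of 189 groups of 9, where the nominal rate is about 1 in 20. That rate is for libraries of 1 population. The 9 libraries come from 3 combinations of line and isolate, so it is not a chance rate for them. The library of pps with A6, replicate 3, at 18 hpi stood above the others for 8 genes of defence signalling. These were MAPKKK19 (4.22 CPM against at most 1.48 in the others), MYB15 (4.64 against 1.72), RHD2 (3.64 against 1.34), EDS5 (40.3 against 21.6), OPCL1 (119 against 81.5), JAZ1 (36.9 against 20.1), LOX4 (25.2 against 14) and ERF1A (14.9 CPM). All 8 were higher in the avirulent libraries at that time. The search covered only named genes, most of them named because they were called in that comparison. Their shared direction was therefore largely fixed by the choice and says nothing further about this library. Replicate 2 of the same group was highest for the receptor-like kinase genes CRK11 (20.9 CPM) and CRK19 (44.5 CPM).

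At 18 hpi replicate 3 of B12 with A6 was far above the other virulent libraries for BBX16 (11.1 CPM), LHCB2.2 (281 CPM), the abscisic acid synthesis gene NCED3 (1.08 CPM) and the asparagine synthetase gene ASN1 (42.9 CPM). Replicate 1 of pps with K1 was so for AT5G12900 (14.8 CPM), TRM28 (4.48 CPM) and the sugar transporter gene SWEET15 (27.7 CPM against at most 0.298), and replicate 3 for AT5G39520 (19.6 CPM) and the cell wall gene PMR5 (10.4 CPM). At 24 hpi replicate 1 of pps with K1 was highest for EDS1B (34.2 CPM) and lowest for GSTF6 (1000 CPM against at least 1240), replicate 3 of that group highest for MRE11 (6.66 CPM), and replicate 1 of pps with A6 highest for MYC2 (26.5 CPM) and MYB15 (4.46 CPM). At 6 hpi ICS1 was at 53.4 CPM in replicate 1 of pps with K1 against at most 11.3. The monooxygenase gene FMO1 was at 0.0186 CPM in replicate 1 of B12 with A6 against 0 in the other 8, near the floor of the counts. At 12 hpi replicate 2 of pps with A6 was highest for PR1 (0.28 CPM) and FMO1 (0.366 CPM).

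Effects that differed between groups were tested directly with edgeR. The avirulence effect differed between the 4 times for 5492 genes, among them WRKY33 (edgeR adjusted p = 5.33e-09), ACS6 (1.27e-08), PAD3 (3.34e-08), PEN2 (8.18e-08), RBOHD (5.91e-07), PAD4 (2.79e-05), CYP71A13 (5.32e-05), PR1 (0.00895) and LOX2 (0.0207). The isolate effect in pps differed between times for 1312 genes and the line effect under A6 for 35. The isolate effect differed between the lines for 12 genes at 6 hpi, 3346 at 18 hpi and 666 at 24 hpi. At 12 hpi it did so for 0 genes in the edgeR test, with 948 at an unadjusted p below 0.05. The count at 24 hpi holds loci of the raised region of chromosome 3, such as AT3G55470.

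Runs of neighbouring loci raised in single libraries touch ICS1 at 6 hpi, EDS1B at 24 hpi and LHCB2.2 at 18 hpi. In the raised region of chromosome 3 the excess followed the number of exons summed over transcripts (Spearman rho 0.928, permutation p = 1e-04, the smallest the permutations can give), and also the level in the other libraries (Spearman rho 0.741), as a gain would. A gain of transcription or copy number by a similar fold is argued against. Of the 38 loci under 1 CPM in the other libraries, 100% exceeded 10 CPM in the raised ones. Loci with 1 annotated exon among these had an excess close to 32.7 CPM (as AT3G55252 and AT3G55550) or to 41.2 CPM (as AT3G55485 and AT3G55790). Such equal steps also argue against a gain by unequal folds at these loci, while it stays open for the expressed loci. Chance placement is argued against, since shuffled orders gave at most 6 loci in runs against 3505. A candidate explanation is that reads with a spliced gap over a region were counted once at every annotated exon inside the gap, which was not tested on reads, and other biological explanations were not tested.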

How the results depend on the processing

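The fits without loci in runs, without the 2 libraries rich in ribosomal RNA and without the 4 libraries with a raised region were chosen only after the results were seen, and the other alternatives before the data were examined. Of 407 named results 328 were called, and 224 of these kept their call and direction in all settings. The values below are those that changed, and the cause was not tested except where stated.

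At 6 hpi the 58 called genes became 293 with DESeq2, 482 without terms for line and isolate, 12 with the interaction contrast, 1868 within the same line, 186 within the same isolate and 10 without loci in runs. The contrast within 1 line holds the isolate effect and the contrast within 1 isolate the line effect. Leaving out single libraries gave 32 to 205: 38 and 32 without B12 with A6, replicates 1 and 2, 125, 205 and 32 without B12 with K1, replicates 1, 2 and 3, 98 without pps with K1, replicate 3, and 105 without pps with A6, replicate 2.

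At 12 hpi the 17 genes became 11 without a filter, 61 with DESeq2, 73 without those terms, 2563 within the line, 28 within the isolate and 5 without loci in runs. The interaction contrast gave 0 in edgeR (948 at an unadjusted p below 0.05). Leaving out single libraries gave 0 to 60: 60, 43 and 0 without B12 with K1, replicates 1, 2 and 3 (944 at an unadjusted p below 0.05 for the last), 10 without B12 with A6, replicate 1, 11 and 10 without pps with K1, replicates 2 and 3, and 11 without each replicate of pps with A6.

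At 18 hpi the 3345 genes became 5047 within the isolate, and 984 with an absolute log2 fold change of at least 1. Leaving out single libraries gave 1872 to 3636, with 1872 and 2130 without B12 with K1, replicates 1 and 2. At 24 hpi the 1936 genes became 2919 without terms for line and isolate, 666 with the interaction contrast, 2990 within the line, 1247 without the libraries with the raised region and 760 with the fold threshold. Leaving out single libraries gave 1112 to 2013, with 1112 without B12 with K1, replicate 2. The 5492 genes whose effect differed between times became 1759 with interaction contrasts, and 4033 to 6133 without single libraries.

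The 99 genes between lines under A6 became 62 without a filter, 378 with DESeq2, 50 without the libraries rich in ribosomal RNA, 39 without those with the raised region and 19 with the fold threshold. Leaving out single libraries gave 58 to 237. These were 58 without B12 with A6 at 6 hpi, replicate 1, 60 at 12 hpi, replicate 3, 59 at 18 hpi, replicate 3, 60 and 237 at 24 hpi, replicates 1 and 2, and 63 without pps with A6 at 24 hpi, replicate 1. The 3472 genes between isolates in pps became 233 with the fold threshold and 2669 to 3785 without single libraries. For virulent interactions at 12, 18 and 24 hpi against 6 hpi the fold threshold gave 6745, 5650 and 4991, and single libraries left out gave 16462 to 16720, 15573 to 15735 and 14597 to 14849.

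Of the 147 list tests 64 passed with the preset correlation, 6 with an estimated one, 74 with fry (49 of the 64 among them) and 68 with the interaction contrast (54 among them). In all 6 the estimated correlation kept the direction.

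Named genes changed direction in 4 settings. AT5G54700 between isolates had a log2 fold change of -0.06 without pps with K1 at 18 hpi, replicate 2, and up to 3.14 without other single libraries. PMR6 at 24 hpi had 0.17 without the libraries with the raised region, PRR5 at 24 hpi -0.05 with the interaction contrast, and RVE1 at 6 hpi -2.18 without B12 with K1, replicate 3, and up to 5.74 without other single libraries. SWEET15 at 18 hpi had 0.00 within the line, where it had no counts in either group.

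Replicates share only a number here. Of 72 pairs of same-numbered libraries of a time, 12 had a correlation of deviations above 0.1, with a median of -0.0147, and 16 of 48 libraries matched best with their own number. With the replicate number as a block (replicate block), the 17 genes at 12 hpi became 10, 65 list tests passed (64 of the 64 among them), and the other counts of genes stayed within 1.5 times. Calls of small changes are limited with 3 against 9 libraries: 26% of genes changed 1.5-fold were recovered in simulated data at 18 hpi.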

Other observations

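The family tests, the correlation of isolate differences between plant lines and the 2 tests of the resemblance at 18 hpi were chosen only after the result was seen, and the clock test of the isolate difference and the splits of the libraries before. Families of genes that share a symbol, some with members in the lists above, were tested by camera in the avirulence comparisons at 18 and 24 hpi, in 266 tests over 133 families. Of 24 ERF genes, which encode ethylene response factors, 16 were higher at 18 hpi and 0 lower (camera adjusted p = 4.8e-13, and adjusted p = 0.0289 with an estimated correlation). Of 54 WRKY transcription factor genes 18 were higher and 0 lower at that time (camera adjusted p = 4.95e-05, but adjusted p = 0.458 with an estimated correlation). Of 50 UGT glycosyltransferase genes 15 were higher and 1 lower (camera adjusted p = 0.000128, but 0.423 with an estimated correlation), and of 23 CPK calcium-dependent kinase genes 8 were higher and 0 lower (0.00028, but 0.458). Of 21 EXO genes, most of them subunits of the exocyst, 9 were higher (0.000598, but 0.458), and so were 9 of 21 PUB ubiquitin ligase genes (0.000598, but 0.458). Among 12 JAZ genes 7 were higher and 0 lower (camera adjusted p = 0.000137, but 0.544 with an estimated correlation). Families with lower members at 18 hpi were IQD, TRM and XTH, each with 0 higher. In IQD 7 of 21 were lower (camera adjusted p = 0.0128, but 0.458 with an estimated correlation) and in TRM 7 of 25 (0.0197, but 0.604). For the XTH cell wall genes it was 5 of 21 (0.0433, but 0.544).

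At 24 hpi 12 of 49 receptor-like protein (RLP) genes were lower and 1 higher in the avirulent interaction (camera adjusted p = 7.14e-05, but adjusted p = 0.458 with an estimated correlation). Of 14 FLA genes, which encode fasciclin-like cell wall proteins, 5 were higher and 0 lower (camera adjusted p = 0.00943, but adjusted p = 0.604 with an estimated correlation). The ERF, WRKY, UGT, JAZ and PUB families share members with the lists and are not independent of them.

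The difference between isolates K1 and A6 recurred in the separate libraries of pps and B12 plants at 12 hpi. Across 16029 genes the Pearson r of the isolate log2 fold changes in the lines was 0.397 (0.745 over 14903 genes outside runs of raised neighbours), which argues against chance differences between libraries. Of the genes called in both lines, 598 were higher under K1 in both (70.6 for independent lists), 599 lower in both (56.2) and 0 opposite in edgeR. Material of 1 isolate collected at another time of day would shift the clock genes along their change from 6 to 18 hpi, and over 17 clock genes the Spearman rho was 0.06 in pps (permutation p = 0.814) and -0.42 in B12 (permutation p = 0.0932), which leaves this open. At 6, 18 and 24 hpi the r between lines was 0.306, 0.0977 and -0.639, and outside runs 0.559, -0.234 and 0.28. The negative value at 24 hpi thus did not persist without those loci, while r at 18 hpi became negative. Calls shared by both lines were 45 higher and 223 lower at 6 hpi, 110 and 56 at 18 hpi, and 30 and 4 at 24 hpi. Opposite calls numbered 3, 236 and 80 at these times. In B12 the isolate difference also holds the recognition of K1, so the lines need not be alike.

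At 18 hpi the avirulent interaction resembled the virulent interactions at 12 hpi. Of 2234 genes higher in the avirulent libraries 1925 were also higher in virulent ones at 12 than at 6 hpi (829 for independent lists) and 140 were lower (847). Among 1111 lower genes 908 were also lower (421). These overlaps are with the change from 6 to 12 hpi, which was called for 75% of tested genes. Virulent libraries at 12 and 18 hpi were not tested against each other, so the overlaps do not show a pattern particular to 12 hpi. Earlier collection by the full difference in time is argued against for these libraries. The clock genes moved 10.3% of the way from the 18 to the 12 hpi virulent level (95% interval 4.93 to 21.2). Early pattern-response genes moved 63.9% (54.5 to 73.5), tryptophan and camalexin genes 74% (65.1 to 81.7) and ethylene genes 56.1% (28.1 to 80.4). Jasmonate genes moved 35.9% (16.1 to 58.3, overlapping the clock interval) and photosynthesis genes 15.7% (10.9 to 21.2). The intervals come from 2000 resamples of the genes of a list, so they hold no spread between libraries. A smaller shift in collection time stays open. Raised counts in runs of neighbouring loci are argued against as the source, since 3320 genes were called without those loci, against 3345. A candidate explanation is that recognition of AVRA1 prolongs or renews the early defence response, which is a hypothesis, since the pattern was found and tested on the same data, and which samples taken more often between 12 and 24 hpi from new plants would test.

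The libraries were also regrouped in 40 splits per comparison, the real one included. For avirulence at 18 and 24 hpi only the real split, 1 of 40 each, gave as many genes. The counts were 3345 against at most 1139 in the others, and 1936 against at most 552. This argues against chance but does not exclude it, since 40 splits cannot show a share below 1 of 40. The same holds for genes whose avirulence effect differed between times (1 of 40, 5492 against 408). For the avirulence list tests 1 of 40 splits gave as many (29 against 27), but the median of the others was 21, so camera with the preset correlation passed nearly as many lists in a typical random split. An earlier, larger draw held higher other values at 12 and 18 hpi and for the effect between times, though the real count stayed highest in the last 2, and it held a few splits with as many lists, so the margin of the list tests is narrow. At 6 and 12 hpi chance cannot be excluded: 32 and 33 of 40 splits gave as many genes, with 58 real against up to 231 and 17 real against up to 121. What makes some splits call several times the real count was not tested.

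For the lines under A6 (1 of 40, 99 genes against 3) and the isolates in pps (1 of 40, 3472 against 1089) chance is argued against, within the limit of 40 splits. Chance is also argued against for genes changed in virulent interactions from 6 hpi to 12, 18 and 24 hpi (1 of 40 each). The counts were 16578 against 12557, 15736 against 14170 and 14759 against 663. For the list tests of these time comparisons the splits cannot decide. As many lists passed in 5, 8 and 4 of 40 splits (13 real and 13 in the highest other at 12 hpi, 10 and 12 at 18 hpi, 12 and 12 at 24 hpi). The median of the other splits was 8, 7 and 7 lists, although their median number of called genes was 0, 0 and 1. The number of lists passed by camera with the preset correlation thus hardly separates the real split from others. No conclusion on chance is drawn from it.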
